A study of Homo sapiens with 2 samples.

How the data were processed

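Single-cell RNA libraries of engineered heart tissues were analysed, 2 biological replicates of 1 group. Per the labels, each library was made with the 10x Chromium 3' V3 kit from tissues pooled over 2 plates of 48 wells, with 5 µg/mL transforming growth factor beta 1 as the labels state it for the first 72 h. The authors deposited UMI counts per gene and barcode, and the values were whole numbers. The counts came from Cell Ranger 7.1.0, per the file headers, and the submitters' processing notes name GRCh38 and Seurat, the latter without a role. The annotation release, the filters on barcodes and any doublet treatment before deposit are not given in the sources used here. The tables list 62104 features, of which 1424 repeat the symbol of an earlier feature, with eGFP as an added transcript. Positions and gene lengths were taken from GENCODE release 29 on GRCh38 through the gene identifiers, which may be another release than the authors used.

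Barcodes with fewer than 500 genes (358 in replicate 1 and 259 in replicate 2) or over 30% mitochondrial UMIs (218 and 102) were removed. Scrublet, as provided in scanpy 1.11.5, called 708 doublets (6.70%) among the barcodes with at least 500 genes in replicate 1 but only 5 (0.0703%) in replicate 2, which counts as a failure of the caller. There the 405 barcodes with the highest doublet scores were taken, from a loading rate of 0.8% per 1000 barcodes. Counts were scaled to 10000 per cell, log-transformed and scaled within each library. The 2000 most variable genes, leaving out every gene of the lists below, the ratio genes and mitochondrial genes, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9). The 20 clusters were named from 10 marker lists fixed beforehand. A name required a marker score of at least 0.4, a second-best score of at most 0.3 of the best, and 3 markers at 100 CPM or more. A cluster with a median UMI count below the library's median divided by 3 also needed a marker of its class among its 10 leading genes. This left clusters 15 and 18 without a name, although they scored 0.574 for cardiomyocyte and 0.509 for fibroblast. The form of this rule and its thresholds were set after seeing the data, and the joint share of the clusters it leaves without a name is given. A score minimum of 0.25 was kept as an alternative. X-inactivation and Y-linked transcripts were left out everywhere.

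UMI counts were summed per library and class, and cardiomyocyte-like sums were compared with fibroblast-like sums (2 against 2) by edgeR 4.0.16 under R 4.3.3. The fit used TMM factors, filterByExpr and the quasi-likelihood test. Benjamini-Hochberg adjustment ran over the 18797 fitted genes that were neither clustering features nor markers. The SE of a log2 difference is its size divided by the square root of the F statistic. Counts of genes leave out clustering features and markers. CPM in this comparison (counts scaled to a total of 1e6) are over the genes that entered it, and other CPM are over all UMIs. Total sums per class ran from 32674977 to 51807013 counts. Classes of the same library come from the same pool of tissues, which pairs them, and their deviations correlated at r = 0.335 across 18797 genes. The fit without this block was the main design and the block its alternative. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. The second form takes its degrees of freedom from the libraries, which are few, so its failure to pass alone says little about correlation between genes. The 15 lists, fixed before the data were examined together with the tests and the rule for named genes, cover hypertrophic cardiomyopathy, dilated cardiomyopathy, association loci, calcium handling, ion channels, chamber genes, fatty acid oxidation, glycolysis, oxidative phosphorylation, extracellular matrix, myofibroblast activation, the transforming growth factor beta pathway, ligands and receptors, cell cycle, and immediate early and stress genes. PROM1 and NPR1 were too low to test. The values of some list members are not reported here. Genes named are, per list, up to 2 per direction (4 in the cardiomyopathy lists) with the largest log2 difference among those past the threshold and of the same sign in both libraries, 8 core sarcomere genes, 5 per direction outside the lists with at least 10 CPM, and members that did not pass where at most 5. Members below this rank that a block or another setting changed are named as well, and were chosen after their values were seen.

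The share of free RNA in a class was estimated from markers of the other class, relative to their level over all barcodes of the library. This share includes the RNA of any mixed droplets left in the class. It was 6.63% and 2.76% of the counts in cardiomyocyte-like and 3.40% and 1.38% in fibroblast-like cells of replicates 1 and 2. Intervals are exact binomial or Poisson at 95% and, like a floor of 3 counts, cover counting error only. On simulated counts for 18883 genes with the means and sizes of these sums, 200 genes of higher expected count were changed. Clustering features and markers among them were left out. The edgeR fit recovered 0% of 46 genes changed 2-fold, 18.2% of 44 changed 4-fold, 65.2% of 46 changed 8-fold and 83.0% of 47 changed 16-fold. It called 5 unchanged genes. In the data 3600 genes were called, which makes the adjustment less strict than in the simulation. These shares therefore do not measure how often real differences were missed. Differences of modest size may still have been missed at this number of libraries. Other settings covered the mitochondrial limit (15% or none), a minimum of 1500 genes, doublets kept, resolution 1.0, joint scaling, replicates left out, thinning, subtraction of free RNA, the block, DESeq2 1.42.0, total-count scaling and no low-count filter. Added after seeing the data were Scrublet's own threshold in both libraries, removal of cells with over 10 markers of the other class per 10000 UMIs, the lower naming score, the block for list tests, cluster 4 against fibroblast-like cells, and cluster 1 against its class without cluster 10. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.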

Results

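Engineered heart tissues are small strips of beating muscle cast around posts from cardiomyocytes and fibroblasts in a collagen gel. Here the cardiomyocytes came from a human induced pluripotent stem cell line that carries eGFP at the AAVS1 safe-harbour locus, were differentiated for 10 days and column-purified, and were mixed with primary human cardiac fibroblasts. The tissues received transforming growth factor beta 1 for the first 72 h and were dissociated 20 days after casting, at day 30 in all. Tissues from 2 plates of 48 wells were pooled for each 3' single-cell RNA library, and the experiment was repeated with an independent differentiation, which gave 1 group of 2 biological replicates with a target of 10000 cells each. Replicate 1 held 10927 barcodes and 147326667 unique transcript counts (UMIs), with a median of 10741 UMIs and 3282 genes per barcode. Replicate 2 held 7370 barcodes and 126279342 UMIs, with medians of 13196 UMIs and 4225.5 genes. After filtering, 9647 and 6604 cells remained.

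Cardiomyocyte-like cells, named from contractile genes such as MYH6, MYL7 and RYR2, made up 36.2% ± 5.42 of the kept cells (SD, n = 2 libraries), and fibroblast-like cells, named from collagens and DCN, made up 32.8% ± 8.43. Cells named for lineages that were not cast on purpose were common in replicate 1 and rare in replicate 2. Clusters left without a name, such as cluster 4 below, are not counted in this. Endoderm-like cells, with AFP at 4626 CPM (counts per 1e6 counts) and the apolipoprotein APOA1 at 15468 CPM in replicate 1, took 9.07% of its cells (exact 95% binomial interval 8.50 to 9.66) and 0.485% of replicate 2 (0.332 to 0.683). A cluster was scored in the library that held most of it, so the endoderm-like name of the 32 cells in replicate 2 was not checked there. Neural-like cells, with the progenitor factor SOX2 at 212 CPM, took 3.89% of replicate 1 and a share of 0.0151% in replicate 2, which was 1 cell. Endothelial-like cells, with the adhesion molecule PECAM1 at 682 CPM, took 2.21% and 0.121%. At a clustering resolution of 1.0 endoderm-like cells were 2.99% and neural-like cells 0.477% of replicate 1, and 3 other settings named no neural-like cluster.

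The share of cardiomyocyte-like cells was 32.4% in replicate 1 (31.4 to 33.3) and 40% in replicate 2 (38.8 to 41.2), and that of fibroblast-like cells was 38.8% and 26.8%. These intervals cover counting error only, and no test was made between the libraries because both belong to the same group. In replicate 1 the cardiomyocyte-like cells lay mainly in clusters 2 and 1 (1834 and 1048 cells) and the fibroblast-like cells in clusters 0 and 6 (2681 and 1056), whereas in replicate 2 they lay in clusters 5 and 1 (1484 and 1032 cells) and in cluster 3 (1720 cells). Clusters left without a name held 13.7% of replicate 1 and 32.5% of replicate 2. The largest of them over both libraries was cluster 4, with collagen transcripts together with SLPI, DLK1 and HAPLN1, at 11.2% and 6.6%. Cluster 8 carried cardiomyocyte and fibroblast markers at once and held 9.81% of replicate 2, and cluster 12, led by cell cycle genes such as UBE2C and MKI67, held 4.91% of it. Cluster 11 held 5.13% of replicate 2, at a median of 3428 UMIs. Fibroblast was the highest marker score of clusters 11 and 12 (0.343 and 0.277), so the lower fibroblast-like share of replicate 2 depends on the naming rule. With the lower naming score, which adds cluster 12, that share was 31.8%, against 38.8% in replicate 1. Cluster 11 stayed out under that setting too, because of the rule on shallow clusters, so 31.8% is not the full extent of this dependence.

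**Figure D1:**
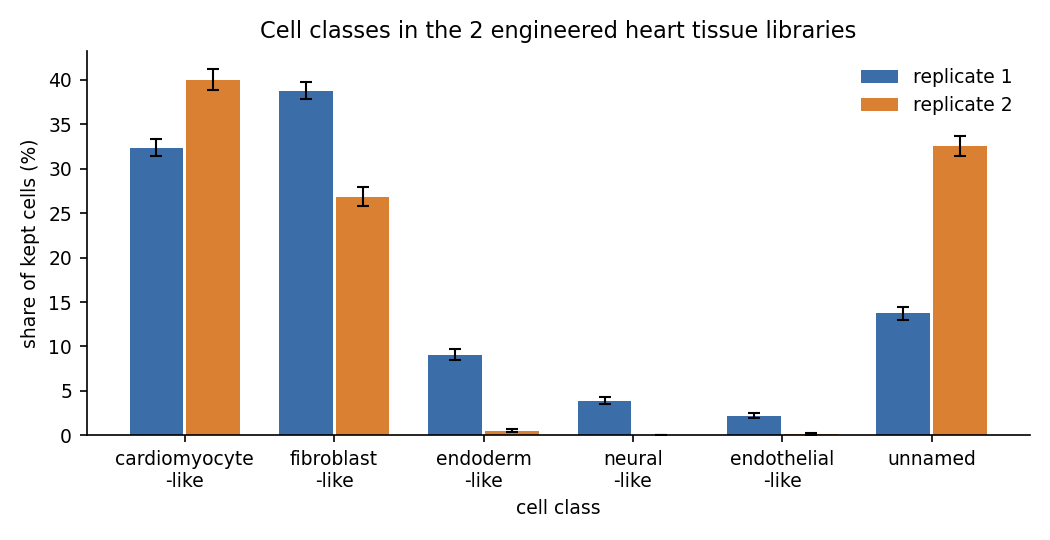
Share of kept cells (percent, vertical axis) in each cell class (horizontal axis) for replicate 1 (blue) and replicate 2 (orange); bars are values of a single library and error bars are exact 95% binomial intervals, which cover counting error only. Cardiomyocyte-like cells took 32.4% and 40%, and endoderm-like cells 9.07% and 0.485%.

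The transgene marks cells that descend from the stem cell line. eGFP stood at 7675 ± 1541 CPM in cardiomyocyte-like cells and at 64.4 ± 40.2 CPM in fibroblast-like cells (SD, n = 2). At least 1 eGFP UMI was found in 91.3% of cardiomyocyte-like cells of replicate 1 and 96.1% of replicate 2, at median depths of 10159 and 10124 UMIs. In fibroblast-like cells the share was 35.9% and 22.7% at median depths of 11583 and 22949 UMIs. Free RNA, the transcripts that leak into every droplet, would at its estimated share give 104 and 36.8 CPM of eGFP in fibroblast-like cells. The measured levels were 92.8 and 35.9 CPM. With cells holding markers of the other class left out, 3562 of 3740 and 1737 of 1773 fibroblast-like cells stayed. The estimated share then fell to 2.01% and 0.635%. Part of the estimate therefore lay in few cells, and the match does not show that eGFP was spread evenly over droplets. eGFP was also present in endoderm-like cells (845 and 1259 CPM), in neural-like cells of replicate 1 (1930 CPM) and in endothelial-like cells (1031 and 2047 CPM). The replicate 2 values rest on 32 endoderm-like and 8 endothelial-like cells, whose names were scored in replicate 1 only.

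**Figure D2:**
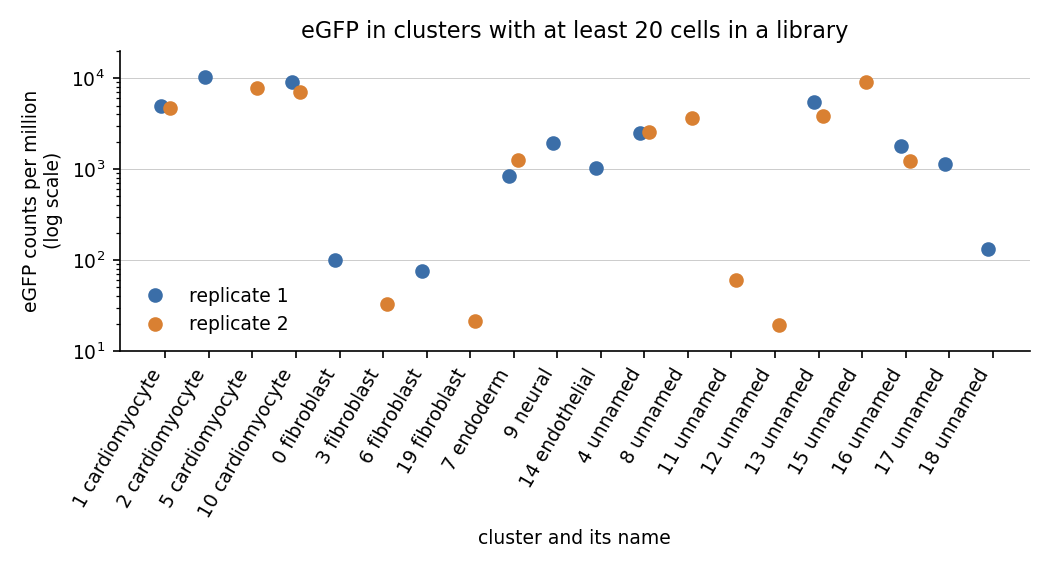
eGFP level (CPM, log scale, vertical axis) in each cluster with at least 20 cells in a library (horizontal axis, with the cluster's name), for replicate 1 (blue) and replicate 2 (orange); each point is the pooled count of 1 library. Cardiomyocyte-like clusters lay between 4650 and 10293 CPM, fibroblast-like clusters between 21.4 and 98.9 CPM, and cluster 4 at 2471 and 2531 CPM.

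The labels name no treatment contrast, so the comparison within these tissues is between their cast cell types, and it asks in which of them the genes of cardiomyopathy are active. Among 18797 tested genes that had no part in defining the classes, 1748 were higher in cardiomyocyte-like cells and 1852 in fibroblast-like cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p under 0.05, 2 libraries per class). With the library as a block the counts were 2100 and 2413. Outside the gene lists, the cardiomyocyte-like side was led by LRRC10, a cardiac leucine-rich repeat protein (log2 difference 7.56 ± 0.75, SE), C10orf71 (7.61 ± 0.63), the ubiquitin ligase gene MARCHF11 (7.67 ± 0.59), the protease inhibitor SPINK5 (7.22 ± 1.39) and the orphan receptor GPR22. GPR22 had 1114 counts in cardiomyocyte-like and 3 in fibroblast-like cells, a ratio of pooled levels of 526 with a counting interval of 180 to 2554. The fibroblast-like side was led by DOCK10, an activator of small GTPases (−8.88 ± 0.89), the hyaluronan synthase HAS1 (−8.08 ± 1.55), the lectin CLEC14A (−8.06 ± 1.06), the proteoglycan SRGN (−7.99 ± 0.68) and the prostacyclin receptor PTGIR (−7.97 ± 1.19). The median absolute log2 difference between the libraries was 0.48 in cardiomyocyte-like and 0.59 in fibroblast-like cells, against 0.84 between the classes. An exact two-sided permutation test of 2 against 2 sums cannot give a p below 0.333, so the calls rest on the model that pools the spread over genes.

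Genes mutated in hypertrophic cardiomyopathy, most of them of the sarcomere, were concentrated in cardiomyocyte-like cells. Of 18 such genes 15 were higher there and 0 lower, and 17 passed when adjusted over the list alone. MYL2, the ventricular regulatory light chain, stood at 5647 ± 4448 CPM in cardiomyocyte-like and 37.0 ± 38.3 CPM in fibroblast-like cells (SD, n = 2), a log2 difference of 6.96 ± 1.45. The adult cardiac troponin inhibitor TNNI3 (535 ± 16.9 CPM) differed by 6.91 ± 0.75, the muscle LIM protein CSRP3 (3434 ± 526 CPM) by 6.80 ± 0.91 and the Z-disc protein ACTN2 (889 ± 88.0 CPM) by 6.79 ± 0.67. Myosin-binding protein C (MYBPC3, 425 ± 98.2 CPM) differed by 6.02 ± 0.94, beta-myosin heavy chain (MYH7, 2724 ± 1786 CPM) by 6.24 ± 1.36, troponin T (TNNT2, 1017 ± 521 CPM) by 6.65 ± 1.02, cardiac actin (ACTC1, 12388 ± 2285 CPM) by 6.71 ± 1.06 and the essential light chain MYL3 (3451 ± 1529 CPM) by 6.52 ± 1.10. Adjusted p of these 9 genes by edgeR's quasi-likelihood test lay between 0.0064 and 0.027. Tropomyosin TPM1, at 13027 ± 3895 and 2341 ± 1002 CPM, did not pass (log2 2.30 ± 0.78, edgeR adjusted p = 0.094), nor did the formin FHOD3 (2.74 ± 0.92, 0.089) and KLHL24, a ubiquitin ligase adaptor (0.72 ± 0.42, 0.29). With the library as a block TPM1 and FHOD3 passed (edgeR adjusted p = 0.040 and 0.043). With free RNA subtracted 14 genes of this list were higher, and MYH7 no longer passed.

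Of 19 genes mutated in dilated cardiomyopathy, 13 were higher in cardiomyocyte-like cells and 0 lower, and 15 were higher and 1 lower when adjusted over the list alone. The 3 cardiomyopathy lists overlap, with 14 genes on more than 1 of them, so their counts and list tests are not independent. Titin, the elastic filament TTN, stood at 9934 ± 5807 CPM in cardiomyocyte-like and 55.9 ± 15.9 CPM in fibroblast-like cells, a log2 difference of 7.15 ± 0.96. The 6 members that did not pass are named here although they exceed the 5 set beforehand: the lamin LMNA (477 ± 99.3 CPM in fibroblast-like and 228 ± 57.0 in cardiomyocyte-like cells, log2 −1.31 ± 0.50), the actin-linker VCL, the desmosome protein DSP, the co-chaperone BAG3, NEXN and TPM1. With the library as a block 15 were higher and 1 lower, as NEXN (log2 1.50 ± 0.23, edgeR adjusted p = 0.022) and TPM1 passed as higher and LMNA as lower (edgeR adjusted p = 0.025). Camera with a preset correlation of 0.01 placed both lists above other genes (adjusted p = 2.2e-20 for hypertrophic and 5.6e-15 for dilated cardiomyopathy). With an estimated correlation the adjusted p was 0.11 for each.

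**Figure D3:**
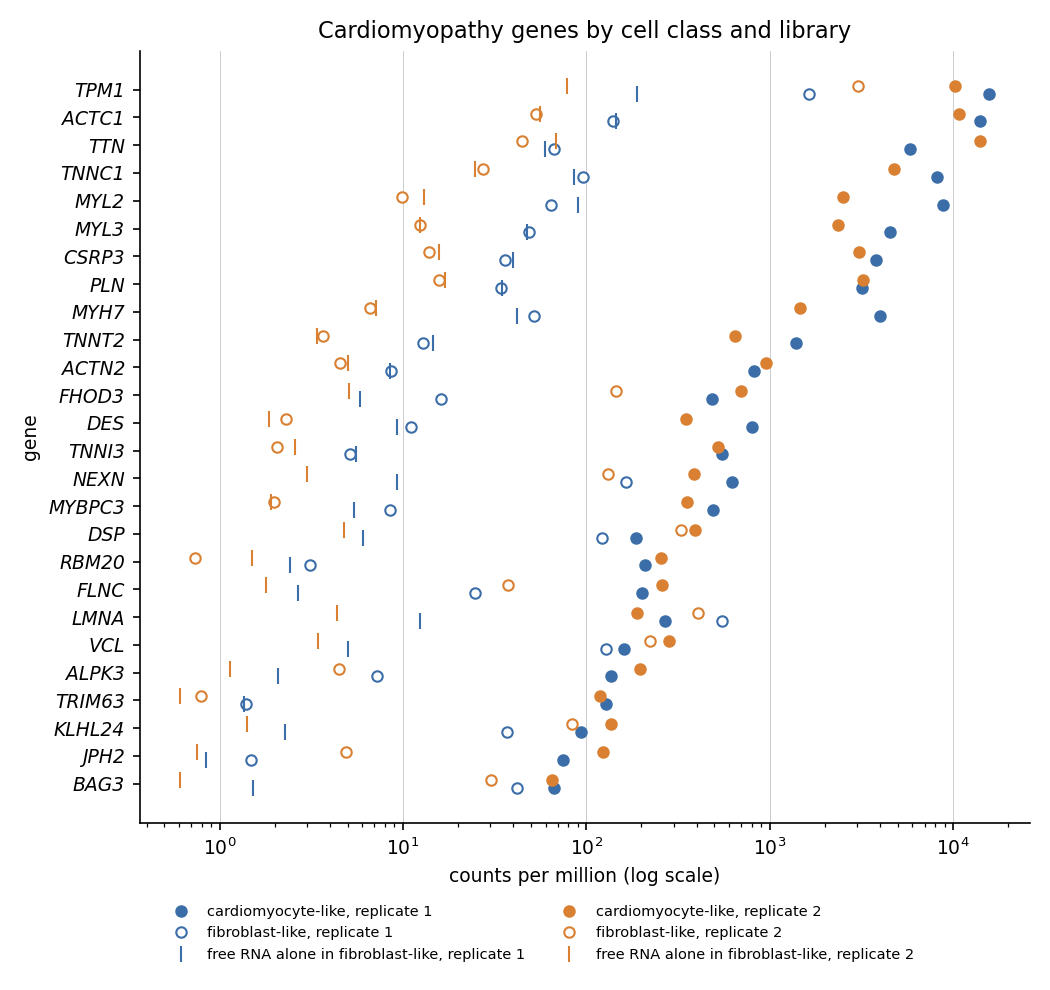
Level of hypertrophic or dilated cardiomyopathy genes (CPM, log scale, horizontal axis; genes on the vertical axis) in cardiomyocyte-like cells (filled) and fibroblast-like cells (open) of replicate 1 (blue) and replicate 2 (orange); vertical ticks give the level free RNA alone would produce in fibroblast-like cells. ACTC1 averaged 12388 CPM in cardiomyocyte-like cells and sat on the free RNA level in fibroblast-like cells, while LMNA, VCL and DSP lay far to the right of their ticks.

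The fibroblast-like level of many of these genes lay near that of free RNA. Of 42 tested genes on the 3 cardiomyopathy lists, 17 lay under 3 times the free RNA level in fibroblast-like cells of both libraries, among them MYBPC3, MYH7, TNNT2 and TTN, and how far these are transcribed in fibroblast-like cells stays open. Another 22 lay at 3 times that level or more in both, among them TPM1 (8.63 and 39.1 times), VCL (25.6 and 64.3), DSP (20.1 and 68.9), LMNA (44.2 and 93.6), BAG3 (27.4 and 49.8) and FLNC (9.24 and 21.0), an actin crosslinker that was still higher in cardiomyocyte-like cells (log2 2.66 ± 0.37).

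Genes named at cardiomyopathy association loci, where noncoding variants lie, leaned toward the cardiomyocyte-like side, though 11 of 21 did not pass. Of 21 tested, 9 were higher in cardiomyocyte-like cells and 1 in fibroblast-like cells, with 11 and 2 when adjusted over the list alone. Beside TTN, the largest differences were those of NRAP, a myofibril assembly protein (8.70 ± 0.21 CPM, log2 7.07 ± 0.69, resting on 3 and 2 counts in fibroblast-like cells), phospholamban (PLN, 3219 ± 16.9 CPM, 6.71 ± 0.82) and ADPRHL1 (77.1 ± 26.9 CPM, 5.37 ± 0.43). CDKN1A, which encodes the cell cycle inhibitor p21, was the gene higher in fibroblast-like cells (167 ± 23.8 against 67.2 ± 16.4 CPM, log2 −1.57 ± 0.35, edgeR adjusted p = 0.030). Total-count scaling ended that call (edgeR adjusted p = 0.072), and PRKCA or TBX3 joined it under other settings, for a range of 0 to 3 genes. The list median was 1.16 and camera gave an adjusted p of 2.7e-05, or an adjusted p of 0.11 with an estimated correlation.

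Many excitation and rhythm genes were higher in cardiomyocyte-like cells, though 7 of 15 calcium handling and 6 of 16 ion channel genes did not pass. Of 15 calcium handling genes 8 were higher there and 0 lower, 9 when adjusted over the list alone, led by PLN, the brake on the calcium pump, and HRC, a calcium-binding protein of the sarcoplasmic reticulum (129 ± 43.6 CPM, log2 5.89 ± 0.77). Of 16 ion channel and gap junction genes 10 were higher and 0 lower, with 12 and 1 over the list alone, among them KCNH2, the rapid delayed-rectifier potassium channel (89.6 ± 3.72 CPM, log2 6.75 ± 0.81). The block added connexin GJA1 as lower (log2 −1.95 ± 0.35) and left 9 higher. Of 15 chamber genes 11 were higher and 2 lower, the same numbers as over the list alone. The transcription factor HAND1 (21.8 ± 4.08 CPM, log2 7.28 ± 0.59) and the atrial hormone NPPA (1035 ± 903 against 6.16 ± 1.37 CPM) were the leading members, and NR2F1 (−5.51 ± 1.13) and NR2F2 (−5.46 ± 1.21), atrial transcription factors also found in stroma, were the members higher in fibroblast-like cells. The calcium pump regulator SLN (log2 1.34 ± 1.66) and the repressor HEY2 (−1.01 ± 0.56) did not pass. Camera adjusted p was 3.1e-07 for calcium handling, 6.2e-11 for ion channels and 2.0e-08 for chamber genes, and the adjusted p with an estimated correlation was 0.11 for each.

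Energy metabolism leaned toward cardiomyocyte-like cells, with list medians of 1.09 for fatty acid oxidation, 1.23 for glycolysis and 1.48 for oxidative phosphorylation. Of 18 fatty acid oxidation genes 4 were higher and 0 lower, also over the list alone, led by the fatty acid binding protein FABP3 (1537 ± 178 CPM, log2 5.23 ± 0.72) and the coactivator PPARGC1A (5.00 ± 0.91). With free RNA subtracted 3 passed, without PPARGC1A (log2 5.52 ± 1.56, edgeR adjusted p = 0.059). Of 18 glycolysis genes 4 were higher and 0 lower (6 over the list alone), led by the insulin-regulated glucose transporter SLC2A4 (5.26 ± 0.69) and muscle phosphofructokinase PFKM (2.65 ± 0.46). Of 25 nuclear-encoded oxidative phosphorylation genes 10 were higher and 1 lower (16 and 1 over the list alone), led by the muscle subunit COX6A2 (6.32 ± 0.56) and the ADP/ATP carrier SLC25A4 (4.85 ± 0.72), with COX7A1 lower (−6.30 ± 1.69, edgeR adjusted p = 0.049). The COX7A1 call was lost under 4 settings, with edgeR adjusted p of 0.051 to 0.057. With the library as a block the higher members numbered 7, 11 and 21. Camera adjusted p was 7.5e-04, 7.6e-05 and 2.8e-07 in this order, and the adjusted p with an estimated correlation was 0.11, 0.31 and 0.21.

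Matrix and myofibroblast genes were higher in fibroblast-like cells. Of 30 extracellular matrix genes 18 were higher in them and 0 in cardiomyocyte-like cells (23 over the list alone), led by the collagen COL6A3 (1004 ± 61.2 CPM, log2 −6.66 ± 1.05) and the microfibril protein FBN1 (700 ± 109 CPM, −6.65 ± 0.77). Of 14 myofibroblast activation genes 9 were higher in fibroblast-like cells (12 over the list alone), led by periostin (POSTN, 4328 ± 1996 CPM, −7.47 ± 0.97) and the surface protease FAP (318 ± 112 CPM, −7.43 ± 0.82), and 1 was higher in cardiomyocyte-like cells, the actin-binding calponin CNN1 (388 ± 69.7 against 58.9 ± 9.88 CPM, 2.51 ± 0.42). Smooth muscle actin ACTA2 (−1.74 ± 0.65), the matrix glycoprotein COMP (−6.39 ± 2.47), LRRC15 (−2.60 ± 0.79) and TNFRSF12A (−0.49 ± 0.49) did not pass, though ACTA2 and COMP did with the library as a block (edgeR adjusted p = 0.018 and 0.0085). Of 17 genes of the transforming growth factor beta pathway 6 were higher in fibroblast-like cells and 0 in cardiomyocyte-like cells (11 over the list alone, 10 with the block), among them the latent-complex protein LTBP2 (175 ± 16.2 CPM, −6.52 ± 0.60). No tissue without the factor was analysed here. Camera adjusted p was 1.0e-15, 1.7e-10 and 1.1e-04 in this order, and the adjusted p with an estimated correlation was 0.11 for each.

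Ligand and receptor genes were found on both sides. Of 28 tested 5 were higher in cardiomyocyte-like and 10 in fibroblast-like cells (5 and 12 over the list alone). On the cardiomyocyte-like side stood insulin-like growth factor IGF2 (1112 ± 89.5 CPM, log2 6.11 ± 0.77) and the beta-adrenergic receptor ADRB1, with 428 counts against 3 and a ratio of pooled levels of 202 (counting interval 68.7 to 984). Interleukin IL6 (439 ± 251 CPM, −7.35 ± 0.91) and hepatocyte growth factor HGF (34.6 ± 30.1 CPM, −6.28 ± 1.02) led the fibroblast-like side. Of 15 immediate early and stress genes 7 were higher in fibroblast-like and 0 in cardiomyocyte-like cells, also over the list alone, led by the chaperone HSPA1A (−5.26 ± 0.41) and haem oxygenase HMOX1 (−4.64 ± 0.52), and the block added the small heat shock protein HSPB1 as higher in cardiomyocyte-like cells (1.36 ± 0.27) and left 6 higher in fibroblast-like cells. Camera adjusted p was 0.013 for ligands and receptors and 7.1e-05 for stress genes, and the adjusted p with an estimated correlation was 0.22 and 0.24.

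**Figure D4:**
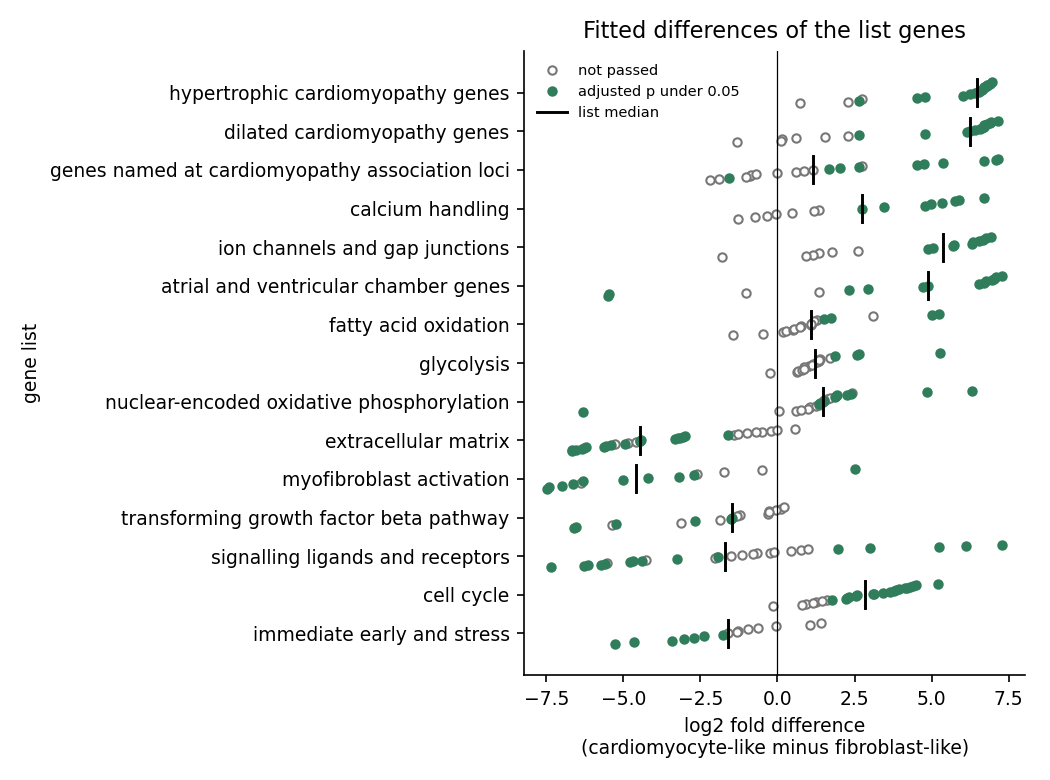
Fitted log2 difference of each list gene (horizontal axis, cardiomyocyte-like minus fibroblast-like; points right of 0 are higher in cardiomyocyte-like cells) for the 15 gene lists (vertical axis); filled points passed edgeR's quasi-likelihood test at an adjusted p under 0.05, open points did not, and black bars are list medians. The medians ran from −4.59 for myofibroblast activation to 6.47 for hypertrophic cardiomyopathy genes.

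Cell cycle genes were higher in cardiomyocyte-like cells than in the fibroblast-like class as named here. Of 26 genes 19 were higher and 0 lower (21 over the list alone), led by the proliferation antigen MKI67 (28.3 ± 8.33 against 0.690 ± 0.621 CPM, log2 5.22 ± 0.77) and the mitotic kinase PLK1 (4.49 ± 0.62). That result hung on cluster 12, the cycling collagen-expressing cells of replicate 2 that stayed without a name. When a lower naming threshold, chosen after seeing the data, placed it in the fibroblast-like class, 0 genes passed edgeR's test and MKI67 differed by 0.33 (edgeR adjusted p = 0.92). With free RNA subtracted 10 genes passed, while the list median was 3.12 against 2.85, and with the block 15 passed. Camera gave an adjusted p of 2.7e-11, or an adjusted p of 0.24 with an estimated correlation. In cells thinned to 3000 UMIs, at least 2 UMIs of 17 G2/M genes were found in 10.0% and 6.26% of cardiomyocyte-like cells of replicates 1 and 2 (8.14% ± 2.65, SD, n = 2) and in 0.273% and 2.71% of fibroblast-like cells (1.49% ± 1.72), or 16.2% of those of replicate 2 once cluster 12 was included. The unthinned shares were 21.8% and 18.2%, and 6.34% and 31.6%, and 375 and 199 cardiomyocyte-like and 72 and 38 fibroblast-like cells were too shallow to thin. The 0.273% of fibroblast-like cells in replicate 1 was 10 cells. Without a mitochondrial limit it was 0.681% (25 cells), although nearly the same cells were kept (3741 against 3740). The unthinned count was 237 cells in both settings. Thinning is a random draw made anew for each setting, so the thinned share also varies with the draw, beyond counting error. Pooled G2/M levels were 541 and 361 CPM in cardiomyocyte-like cells against 26.2 and 70.8 CPM in fibroblast-like cells. How much of the per-cell calls comes from free RNA was left open.

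Paired genes that mark chamber and maturity had different ratios in the replicates. MYH7 (ENSG00000092054, chromosome 14, positions 23412738 to 23435718 of GRCh38) supplied 74.5% of the counts of MYH7 and its neighbour MYH6, the alpha-myosin heavy chain (ENSG00000197616, 23381990 to 23408277), in cardiomyocyte-like cells of replicate 1 (exact 95% binomial interval 74.3 to 74.7) and 30.6% in replicate 2 (30.3 to 30.8), with a mean of 52.5% ± 31.1 (SD, n = 2). Ventricular MYL2 (chromosome 12, 110910819 to 110920722) supplied 27.9% and 15.5% of the counts of MYL2 and atrial MYL7 (chromosome 7, 44138864 to 44141332), with a mean of 21.7% ± 8.75. TNNI3 (chromosome 19, 55151767 to 55157773), the adult troponin I, supplied 6.27% and 10.8% of the counts shared with the fetal TNNI1 (chromosome 1, 201403768 to 201429866), with a mean of 8.54% ± 3.21. The cells came mainly from cluster 2 in replicate 1 and cluster 5 in replicate 2, with cluster 1 in both. The same shares in fibroblast-like cells were 73.8% and 27.5% for MYH7, 22.7% and 12.7% for MYL2, and 5.28% and 7.57% for TNNI3. Over the last 500 bases of their transcripts, 55 of 441 words of 60 bases from MYH7 also occur in MYH6, where counting could mix them, and none do in the other pairs.

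**Figure D5:**
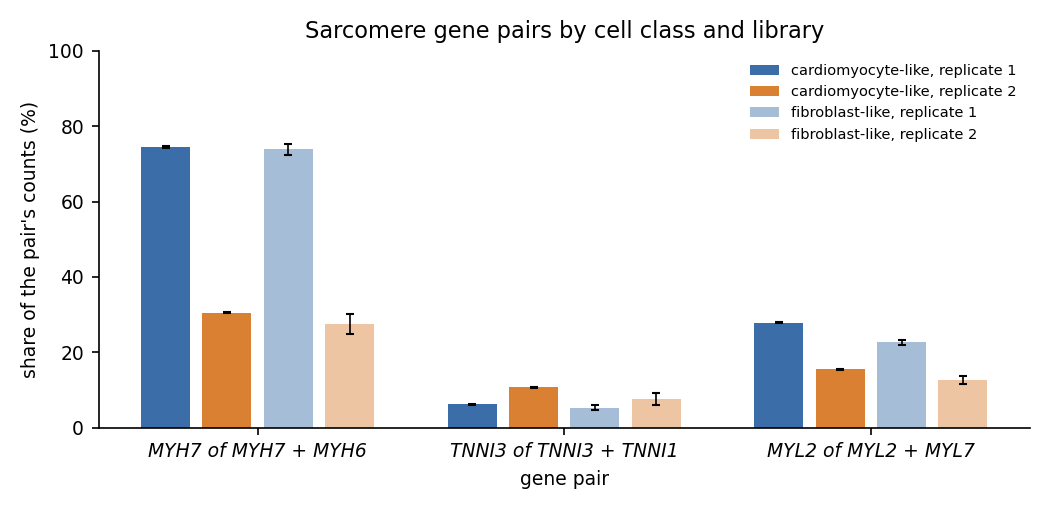
Share of each pair's counts that came from the first gene (percent, vertical axis) for 3 gene pairs (horizontal axis) in cardiomyocyte-like (dark) and fibroblast-like cells (light) of replicate 1 (blue) and replicate 2 (orange); error bars are exact 95% binomial intervals, which cover counting error only. MYH7 took 74.5% in replicate 1 and 30.6% in replicate 2.

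Within the cardiomyocyte-like class, 2 clusters had at least 50 cells in both libraries and were tested against the rest of the class. Cluster 10, led by mitotic genes such as TOP2A, CENPF and CCNB1, had 190 genes higher and 0 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (1199 at an unadjusted p under 0.05), and 1762 higher and 1187 lower with the library as a block. Of 26 cell cycle genes 20 were higher, with a camera adjusted p of 4.2e-154 and an adjusted p of 0.17 with an estimated correlation. Cluster 1, led by long channel and calcium genes such as RYR2, CACNA1C and SLC8A1, had 0 genes past edgeR's threshold in either direction (4096 at an unadjusted p under 0.05), and 3639 higher and 3129 lower with the library as a block. Because the rest of the class holds the mitotic cluster 10, cluster 1 was also compared with the class without it, a comparison added after seeing the data. Again 0 genes passed edgeR's test (4088 at an unadjusted p under 0.05; 3553 and 2909 with the block), and cell cycle genes did not differ as a list (median log2 0.21, camera adjusted p = 0.89). Camera placed oxidative phosphorylation (adjusted p = 3.2e-06), glycolysis (5.0e-04), stress (0.0054) and myofibroblast genes (0.040) lower in cluster 1, and none passed with an estimated correlation (adjusted p of 0.64). The median mitochondrial share was 7.41% in cluster 1 against 2.48% in cluster 2 of replicate 1, and 6.18% against 6.56% in cluster 5 of replicate 2. The clusters were found in the same counts that these tests use, and calls that appear with the block rest on pairing the clusters of the same library.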

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

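All tests in this part were chosen after the results they examine had been seen. The weighing concerns 2 clusters that stayed outside the comparison of cell classes, and no biological explanation from the design was tested, since the labels give a single group.

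Cluster 4, with collagen transcripts, lay outside both cast cell classes and carried eGFP at 2471 CPM in replicate 1 and 2531 CPM in replicate 2, against 92.7 and 35.9 CPM in fibroblast-like cells. Cardiomyocyte RNA in fibroblast droplets would bring cardiomyocyte transcripts in the same proportion as eGFP, but the median of 12 cardiomyocyte markers reached at most 12.58% of the cardiomyocyte-like level while eGFP reached 28.2% and 38.5%. Evenly spread free RNA is argued against as well, since eGFP stood at least 26.66 times above fibroblast-like cells. COL1A1 (2533 and 2117 CPM) and GATA4 (215 and 253 CPM) were present, and the marker scores were 0.338 for neural and 0.289 for fibroblast cells, so the cell type was not settled. A candidate explanation is descent from the stem cell line, not from the added fibroblasts, which stays a hypothesis because these cells were found and tested in the same data.

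Cluster 8 of replicate 2, with 9.81% of its cells, carried fibroblast markers at 39.7% of the fibroblast-like level and cardiomyocyte markers at 58.3% of the cardiomyocyte-like level. For cluster 8 a whole cardiomyocyte with a whole cell of the named fibroblast-like class is argued against by depth. Of those fibroblast-like cells, 8.63% had totals at or below the cluster's median of 9672.5 UMIs. The named class leaves out the shallow cluster 11 (339 cells of replicate 2, median 3428 UMIs), whose highest score was fibroblast. Pairs with such cells were not tested. Free RNA at its usual level is argued against too, as the fibroblast-type UMIs per droplet were 12.15 times the free UMIs of clean cells. A mix of RNA of both types may account for the profile. Of genes at 50 CPM or more, 0.26% exceeded both classes by over 2-fold, against 5.37% in cluster 4. A subset of either class could also give a low share, so this measure cannot single out a mix. The best-fitting sum of the 2 class profiles had weights of 0.695 for cardiomyocyte-like and 0.327 for fibroblast-like cells. Of 3795 genes, 98.2% lay within 2-fold of that sum, which was fitted to the same counts. Partial cells, fused cells and a local excess of debris are not separated by these values, though LRRC75A (167 CPM against 13.1 and 16 CPM) exceeded both classes, and whole pairs were not tested in cluster 13 (3.68% of replicate 2), which also carried both marker sets at a median of 29349 UMIs.

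Lineages outside the cast cell types carried signal in replicate 1: endoderm-like cells were 9.07%, neural-like cells 3.89% and endothelial-like cells 2.21% of its kept cells, and at a clustering resolution of 1.0 endoderm-like and neural-like cells were 2.99% and 0.477%.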

How the results depend on the processing

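Scrublet's own threshold, removal of cells with markers of the other class, the lower naming score and the block for list tests were chosen after seeing the data. Over all settings, these included, no call shared with the comparison as reported changed sign. The ranges that follow also include them, and the lowest cardiomyocyte-like share came with removal of cells with markers of the other class. The share of cardiomyocyte-like cells ran from 33.2% to 37.9% and that of fibroblast-like cells from 30.9% to 35.7%, and MYH7, MYL2 and TNNI3 shares stayed within 52.3% to 53.4%, 21.6% to 22.2% and 8.45% to 8.63%, all within 1 SD between the libraries. That limit is wide, since the SD of the MYH7 share was 31.1. The minor lineages of replicate 1 were less stable: at resolution 1.0 endoderm-like cells were 2.99% and neural-like cells 0.477%, the rest staying without a name, and with a mitochondrial limit of 15%, doublets kept or joint scaling no cluster was named neural-like. Genes higher in cardiomyocyte-like cells numbered 1547 to 2330 and genes higher in fibroblast-like cells 1566 to 2783. The 1547 came with the lower naming score, and the 2783 came without a filter on low counts, which also raised the number of genes tested. Total-count scaling moved the median log2 of all genes from −0.051 to 0.189 and the cardiomyocyte-like part of the calls from 48.6% to 57.2%. Hypertrophic cardiomyopathy genes higher in cardiomyocyte-like cells numbered 14 to 17, dilated cardiomyopathy genes 12 to 15 and association-locus genes 9 to 11.

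Association-locus genes higher in fibroblast-like cells numbered 2 with a mitochondrial limit of 15%, with at least 1500 genes per cell, with doublets kept and with Scrublet's own threshold, 3 with DESeq2 or without the low-count filter, and 0 with total-count scaling by edgeR, where 6207 genes passed an unadjusted p under 0.05. The cause was not tested. Without thinning the share of cycling cells averaged 20.0% in cardiomyocyte-like and 19.0% in fibroblast-like cells, because deeper cells hold more UMIs, and the lower naming score, which adds a cycling cluster, gave 8.27% in fibroblast-like cells. With an estimated correlation 0 of 15 list tests by camera passed at an adjusted p under 0.05, where the preset passed 15, and the block with the preset passed 15. The form with an estimated correlation has few degrees of freedom here, so its failures alone do not show that correlation undoes the results. For chamber genes, with an estimated correlation of −0.002, camera's unadjusted p rose from 9.5e-09 to 0.026. Other lists had estimates far above the preset of 0.01. These were 0.726 for cell cycle, 0.555 for glycolysis, 0.349 for stress and 0.243 for oxidative phosphorylation genes. The remaining lists lay between −0.059 and 0.196. For lists with a high estimate, the preset p may be too small, and their list results stay open. The replicate block gave 6768 genes between cluster 1 and the rest of its class in place of 0, and 2949 for cluster 10 in place of 190. It also gave 1 calcium handling gene lower in cardiomyocyte-like cells in place of 0, and its other changes to list counts are not all given here.

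Of 52 named list genes, 42 kept their direction and side of the threshold under every setting run, 0 values reversed, 9 values fell short of the threshold and 13 passed it. When free RNA was subtracted MYH7 (log2 8.73, edgeR adjusted p = 0.071) and PPARGC1A (5.52, 0.059) fell short. With a single library left, the cardiomyocyte-like share was 32.4% to 40%, the fibroblast-like share 26.8% to 38.8%, the MYH7 share 30.6% to 74.5%, the MYL2 share 15.5% to 27.9%, the TNNI3 share 6.27% to 10.8%, and cycling cells 6.26% to 10.0% and 0.273% to 2.71%. Counts of genes have no value with a single library, since no residual degrees of freedom remain.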

Other observations

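All tests in this part were chosen after the results they examine had been seen, and differences between the libraries were not tested, since both replicates belong to the same group.

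The fibroblast-like cells differed between the replicates more than the cardiomyocyte-like cells did. Of 3671 genes at 50 CPM or more, 92 were over 4-fold higher in replicate 2 and 79 in replicate 1, against 10 and 14 of 3741 in cardiomyocyte-like cells. Replicate 2 (cluster 3) had more transcripts of the inflammatory cytokine IL1B (360 against 13.6 CPM), the neutrophil attractant CXCL8 (1116 against 129 CPM) and the collagenase MMP1 (191 against 5.76 CPM). Replicate 1 (clusters 0 and 6) had more of NDUFA4L2, a subunit homologue induced by low oxygen (1752 against 3.03 CPM), the matrix genes COMP (169 against 2.32 CPM), DPT (138 against 1.41 CPM) and ELN (133 against 3.01 CPM), and the protease inhibitor TIMP1 (17383 against 2027 CPM).

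In cardiomyocyte-like cells, natriuretic peptides were higher in replicate 2, with NPPA at 1672 against 396 CPM and NPPB at 3762 against 1007 CPM, as was the vascular ligand ANGPT1 (125 against 6.62 CPM). MYL2 was lower there (2499 against 8782 CPM), and TTN was higher (14027 against 5821 CPM). Among the 32 endoderm-like cells of replicate 2, the pluripotency factor POU5F1 had 193 UMIs (350 CPM), against 0 UMIs in the 875 cells of replicate 1, where a floor of 3 counts applies. Their pooled G2/M level was 1880 CPM, against 608 CPM in replicate 1. The endoderm-like name was scored in replicate 1, so the cell type of these 32 cells was not settled. Cluster 4 compared with fibroblast-like cells, a comparison added after seeing the data, gave 0 genes past edgeR's threshold (2818 at an unadjusted p under 0.05), and 0 with the replicate block (4485). SLPI (219 and 606 CPM against 1.81 and 0.199 CPM) and the neuropeptide VIP (160 and 116 CPM against 0.462 CPM in replicate 1 and 0 UMIs in replicate 2) were among its leading genes.

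Cluster 1 of the cardiomyocyte-like class had more of the nuclear RNA MALAT1 than the rest of the class (44032 against 3701 CPM in replicate 1, 24018 against 6160 CPM in replicate 2), more CACNA1C and RYR2, and less MYL7 (11029 against 26777 and 9618 against 15872 CPM). Across genes, which are not independent replicates, the log2 difference followed genomic gene length with a Spearman rho of at least 0.736, which is consistent with droplets richer in nuclear RNA, where unspliced long genes are counted through their introns. In replicate 1 cluster 1 was also shallower (median 7207.5 UMIs against 10839 in cluster 2) and had a higher mitochondrial share (7.41% against 2.48%), whereas in replicate 2 it was close to cluster 5 (9917 against 9902 UMIs, 6.18% against 6.56%), so lower cell quality is not excluded in replicate 1. After adjustment for length, calcium handling and ion channel genes still had medians above most matched random lists, at the 97.98th percentile or higher, but the medians fell to 0.14 and 0.06 from 0.71 and 0.18. A small difference in these genes beyond length therefore stays open beside nuclear RNA, which may account for most of the pattern.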
